A study of Homo sapiens with 24 samples.

How the data were processed

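Human coronary artery endothelial cells, primary cells grown for a few passages, were exposed to X-rays or left unexposed. Per the labels' protocols, a total of 10 Gy was given either at once or as 5 fractions of 2 Gy, 2 fractions a day and 6 h apart. RNA was collected 6 h or 24 h after the single or last dose, and each protocol had its own controls. There were 8 groups of 3 samples, and each of the 24 samples was hybridized to 1 one-colour array of 44495 spots.

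The authors read the arrays with Agilent Feature Extraction 9.5.3.1, per the file headers. The deposited array files give the processed spot signal, a background-subtracted and detrended intensity with no scaling between arrays, per the file headers. They also give the mean signal and local background intensity of each spot and marks for spots that were outliers, saturated or well above background. The deposited value table holds, per array, a ratio of signal to a reference value of that array. Compared with the array files, that reference was the 75th percentile of the signal, and the table is linear, with 2 decimals. Probe coordinates are on hg18, per the file headers. No annotation of that build was at hand, so RefSeq gene records of assembly GRCh38.p14 served for names only. Of 34127 distinct probes, 24827 were named through their accession, 1276 had a current symbol, 500 were renamed through a single synonym, 2834 kept the symbol of the file and 4690 had none.

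The processed signal was taken to log2 and the 75th percentile of the non-control spots of the same array was subtracted. Outlier spots were left out, and repeated spots of a probe were averaged. XIST and Y-linked genes were left out of all tables. A probe was used if it was well above background on all arrays of at least 1 group, which left 19965 probes. Where a gene had several, the probe with the highest mean signal stood for it. This gave 16043 genes or transcripts, 14418 of them with a gene symbol. The 75th percentile of the signal ranged from 248.8 to 1594.9 between arrays, with a median of 457.6, and 47.5% to 69.9% of spots were well above background. No probe was saturated on all arrays of a group. Pearson's r across genes, which are not independent replicates, was 0.925 to 0.991 between replicates of a group and 0.849 to 0.991 between arrays of different groups.

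Groups were compared with limma 3.58.1 in R 4.3.3, in 1 model with a mean for each of the 8 groups over all 24 arrays, with 16 residual degrees of freedom and a prior of 1.79. Tests were two-sided, and a gene was called if its Benjamini-Hochberg adjusted p was under 0.05. The 9 contrasts were irradiated against control in each protocol and time, the difference of these changes between protocols at each time, the difference between times in each protocol, and the controls of 1 protocol against those of the other. Errors of log2 changes are standard errors of this model. The number of arrays limits the precision. The labels do not say whether replicates were separate cultures or donors, so p-values measure the spread between these samples. Where a gene was well above background on no array of a group, its fold is given as a lower bound (at least N-fold). The bound uses, on each of those arrays, the gene's signal or that of the dimmest probe well above background, whichever is higher.

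A total of 31 gene lists were fixed before the data were examined. They hold p53 target genes, homologous recombination and Fanconi genes, damage sensing and end joining genes, G1/S and DNA replication genes, mitotic genes, replication-dependent histone genes, type I interferon response genes, antigen processing and presentation genes, inflammatory cytokine and chemokine genes, NF-kappaB regulator genes, leukocyte adhesion genes, endothelial identity genes, Notch pathway genes, TGF-beta and endothelial-mesenchymal transition genes, coagulation and fibrinolysis genes, NRF2 oxidative stress genes, unfolded protein and integrated stress response genes, heat shock genes, immediate early genes, cholesterol synthesis and uptake genes, TNF receptor family and apoptosis genes, senescence and secretory genes, angiogenic growth factor and receptor genes, hypoxia and glycolysis genes, reference genes and cytosolic ribosomal protein genes. Another 5 hold markers of smooth muscle, fibroblasts and pericytes, leukocytes, lymphatic endothelium and epithelium. Lists with at least 4 measured members were tested against all other genes with limma's camera at an inter-gene correlation of 0.01, with an estimated correlation as the alternative, and with Benjamini-Hochberg adjustment over the lists of a comparison. The lymphatic and epithelial lists had 2 measured members each and were not tested.

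The rule for named genes was also fixed before the data were examined. For each irradiated group against its controls it takes the 8 largest rises and the 8 largest falls among called genes whose irradiated and control arrays did not overlap. From each list it takes up to 3 called members with the smallest p, or up to 2 with the largest change where none was called. It also takes CDKN1A, MDM2, GDF15, CCNB1, MKI67, ICAM1, IL6, CXCL8, IFIT1 and PECAM1. For the other contrasts it takes the 5 largest positive and the 5 largest negative differences and the list members. Probes with more than 1 symbol or with none were not named.

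The headers place the arrays on 7 slides, scanned on 4 days. Every control array shared its slide with the irradiated array of the same protocol, time and replicate number. The replicate numbers were checked for pairing by the correlation across genes of the deviations of same-numbered arrays from their group means. At 6 h it was 0.893, 0.724 and 0.840 in the single-dose pairs and 0.319, 0.189 and 0.257 in the fractionated pairs, so the numbers were taken to pair these samples. The pairs also share a slide, and only slides 6 and 7 held 2 pairs of the same protocol and time. Slide and number were not separated here. The main fit kept the groups alone, and a block for the numbers was an alternative. At 24 h at least 1 pair of each protocol lay under 0.1, and the numbers were taken as shared numbers only.

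Alternatives were another background correction (normexp with an offset of 50), quantile normalization, scaling by the median, no filter on dim probes, a filter on all arrays, the mean of a gene's probes, a fit of the compared groups alone, an intensity trend in the prior, blocks for replicate, slide and scan day, array weights, the values of the deposited table, and leaving out each array in turn. The overlaps were also taken at an adjusted p under 0.01, and the lists were also tested with limma's fry. Leaving out slide 4 was added after the data were seen. The fit was tested on simulated data with 200 changed genes among 16043. For the single dose at 6 h it recovered 37 of 67 genes changed by 1 on the log2 scale and 57 of 66 changed by 2, with 6 false calls. For the difference between times in the fractionated protocol it recovered 19 of 67 and 44 of 66, with 3 false calls. The simulated noise was independent between genes and arrays, without slide or pair effects or a background limit, so these rates hold for such data only. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.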

Results

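Gene expression was measured in human coronary artery endothelial cells, which line the arteries of the heart, after X-rays given as 1 dose of 10 Gy or as 5 fractions of 2 Gy. Cells were collected 6 h or 24 h after the single or last dose, with separate controls for each protocol. Each of the 8 groups had 3 arrays, and 16043 genes or transcripts were tested. The 75th percentile of an array's signal lay between 248.8 and 1594.9. Below, a change is a log2 difference, irradiated minus control, followed by its standard error, with 3 arrays in each group. The error comes from the model of all 24 arrays, so a gene has the same error in all 4 comparisons. It is not the spread of the arrays compared. An array's mean r with its other replicates was 0.932 to 0.968 for the single dose and 0.964 to 0.990 for the fractions. Counts of called genes thus do not measure the size of a response alone. For every gene named by the rule as having risen or fallen, the 3 irradiated arrays lay beyond the 3 control arrays. List tests are from camera, with a second adjusted p that estimates the correlation within the list from these arrays.

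**Figure D1:**
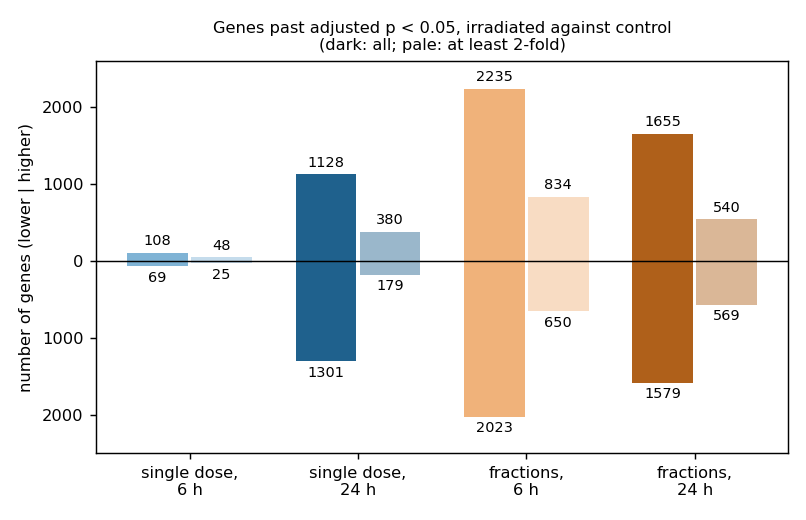
Number of genes past an adjusted p of 0.05 in limma, irradiated against control, for each protocol and time. Bars above 0 count higher genes and bars below 0 lower genes, in dark for all and in pale for changes of at least 2-fold; the fractions at 6 h gave the most, 2235 higher and 2023 lower.

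The first comparison asked what changed 6 h after the single dose. Genes that p53 switches on after DNA damage rose, and genes of mitosis fell. FAS, a death receptor, rose by 2.13 ± 0.09, a 4.38-fold change, from -0.88 ± 0.14 (SD, n = 3) relative to the 75th percentile to 1.25 ± 0.05 (SD, n = 3). Its probe, A_23_P63896, lies on chromosome 10 from 90764525 to 90764584 in hg18. MDM2, which marks p53 for breakdown, rose by 1.87 ± 0.23, the cell cycle inhibitor CDKN1A by 1.63 ± 0.27 and the secreted stress factor GDF15 by 1.70 ± 0.28. Of 40 measured p53 target genes, 28 rose and 0 fell, and 37 rose when adjusted over the list alone. The list median was 0.97, and it was 0.84 to 1.06 in the 3 pairs of arrays that shared a slide (camera adjusted p = 9.43e-94, and adjusted p = 6.9e-06 with an estimated correlation).

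Among 40 mitotic genes, 12 fell and 0 rose 6 h after the single dose, and 35 fell when adjusted over the list alone. The list median was -0.90 (camera adjusted p = 4.46e-56, and adjusted p = 0.0126 with an estimated correlation). The mitotic kinase PLK1 changed by -1.997 ± 0.27, the kinase AURKA by -1.55 ± 0.20, cyclin B1 (CCNB1) by -1.42 ± 0.20 and the anaphase activator CDC20 by -1.76 ± 0.26. The proliferation marker MKI67 had a change of -1.18 ± 0.38 that did not pass (adjusted p = 0.273). Of 37 G1/S and DNA replication genes 5 fell, among them the helicase subunit MCM6 at -0.89 ± 0.11 and cyclin E1 (CCNE1) at -0.80 ± 0.13, and 9 fell and 1 rose when adjusted over the list alone (median -0.34, camera adjusted p = 1e-15, and adjusted p = 0.0474 with an estimated correlation).

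Some NF-kappaB regulator and inflammatory genes also rose at this time. ATF3, a transcription factor of the stress response, rose by 2.57 ± 0.39. Of 20 NF-kappaB regulator genes 3 rose, 6 when adjusted over the list alone (median 0.32, camera adjusted p = 8.49e-13, and adjusted p = 0.000898 with an estimated correlation). RELB changed by 1.65 ± 0.25. TRAF1 of the same list was well above background on no control array and was at least 2.56-fold higher after the dose. Of 26 inflammatory cytokine and chemokine genes 2 rose, LIF at 1.63 ± 0.37 and IL1A at 0.96 ± 0.22, and 8 when adjusted over the list alone (median 0.47, camera adjusted p = 4.05e-08, and adjusted p = 0.000898 with an estimated correlation). Of 30 TNF receptor family and apoptosis genes 2 rose, TNFSF9 at 1.49 ± 0.17 and TNFSF4 at 0.73 ± 0.14, and 4 when adjusted over the list alone (median 0.19, camera adjusted p = 1.83e-07, and adjusted p = 0.000898 with an estimated correlation). No interferon response gene of 36 was called with limma, with or without adjustment over the list alone, and the list median was 0.26 (camera adjusted p = 1.38e-05, but adjusted p = 0.336 with an estimated correlation). With a block for the replicate numbers, which pair the samples at 6 h, 4 rose, 8 when adjusted over the list alone (camera adjusted p = 8.66e-07), and with a slide block 0 (0.000863). Of the 36 genes 31, 28 and 32 were higher in the 3 pairs. IFIT1, an antiviral gene induced by interferon, had a change of 0.34 ± 0.59.

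In total 177 genes passed at 6 h after the single dose, 108 higher and 69 lower, and 73 of them changed at least 2-fold. The groups did not overlap in all 177, against 9.82% of all genes and 10% by chance. A slide block gave 612 genes, and a block for the replicate numbers 766. With the latter 37 p53 target, 8 NF-kappaB regulator, 6 inflammatory and 7 TNF receptor family genes rose, 22 mitotic genes fell, and 12 G1/S and DNA replication genes fell and 1 rose. The count fell to 27 with normexp (44.4% higher, against 61.0%), to 52 with median scaling (50% higher), to 96 without control replicate 3 and to 116 without irradiated replicate 3. In a fit of these 6 arrays alone limma called 0 genes (726 at an unadjusted p under 0.05), so every call named above was lost there, and those of GDF15, MCM6, CCNE1, LIF, IL1A, TRAF1, TNFSF9 and TNFSF4 were also lost with normexp. Leaving out irradiated replicate 4 took LIF to an adjusted p of 0.203, IL1A to 0.174 and TNFSF4 to 0.0631, leaving out control replicate 3 took them to 0.153, 0.22 and 0.0741, and leaving out irradiated replicate 1 took LIF to 0.0641, IL1A to 0.155 and TRAF1 to 0.0535. LIF was also lost without control replicate 1 (0.148), and IL1A without any other array, at 0.0536 to 0.101.

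The second comparison asked what changed 24 h after the single dose. The p53 target genes were still higher, genes of DNA replication were lower, and inflammatory genes were higher in larger number. Of the 40 p53 target genes 34 rose and 0 fell, 35 when adjusted over the list alone (median 1.02, 0.94 to 1.06 in the 3 pairs, camera adjusted p = 2.74e-26, and adjusted p = 0.00552 with an estimated correlation). CDKN1A rose by 2.14 ± 0.27, FAS by 1.68 ± 0.09, GDF15 by 1.78 ± 0.28 and MDM2 by 1.49 ± 0.23. Of the 37 G1/S and DNA replication genes 29 fell and 0 rose, 31 when adjusted over the list alone (median -0.91, camera adjusted p = 3.12e-23, and adjusted p = 0.0199 with an estimated correlation). MCM6 changed by -1.93 ± 0.11, MCM2 by -1.48 ± 0.16 and MCM3 by -1.18 ± 0.11. Of 40 mitotic genes 21 fell, 31 when adjusted over the list alone (median -0.75, camera adjusted p = 4.44e-15, but adjusted p = 0.191 with an estimated correlation). MKI67 changed by -1.91 ± 0.38 and CCNA2, a cyclin of S phase and G2, by -1.06 ± 0.20.

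DNA repair genes also fell, in part. Of 20 homologous recombination and Fanconi genes 13 fell and 0 rose, 15 when adjusted over the list alone (median -0.74, camera adjusted p = 4.21e-10, and adjusted p = 0.0432 with an estimated correlation). BARD1 changed by -1.17 ± 0.19 and FANCI by -0.78 ± 0.14. Of 19 damage sensing and end joining genes 6 fell, 7 when adjusted over the list alone (median -0.31, camera adjusted p = 6.98e-05, and adjusted p = 0.00651 with an estimated correlation). The histone variant H2AX changed by -1.21 ± 0.24. Among 36 genes of the replication-dependent histone list 12 fell and 1 rose, 15 and 2 when adjusted over the list alone. The histone list median was -0.41 but 0.26 with normexp (camera adjusted p = 7.02e-07, but adjusted p = 0.0834 with an estimated correlation). H4C3 changed by -2.45 ± 0.13, a 5.45-fold fall, and H4C4 by -3.05 ± 0.31. Of 16 heat shock genes 8 fell, 9 when adjusted over the list alone (median -0.37, camera adjusted p = 5.41e-05, and adjusted p = 0.0432 with an estimated correlation). HSPE1 changed by -0.63 ± 0.13.

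Of the 26 inflammatory cytokine and chemokine genes 15 rose and 0 fell 24 h after the single dose, 17 when adjusted over the list alone (median 0.96, 0.84 to 1.10 in the 3 pairs, camera adjusted p = 1.22e-08, and adjusted p = 0.00224 with an estimated correlation). LIF rose by 2.45 ± 0.37 and the monocyte attractant CCL2 by 1.12 ± 0.13. Of 20 NF-kappaB regulator genes 6 rose, 10 when adjusted over the list alone (median 0.58, camera adjusted p = 0.000242, and adjusted p = 0.0432 with an estimated correlation). RELB changed by 1.41 ± 0.25. Of 15 leukocyte adhesion genes 5 rose, 6 when adjusted over the list alone, with ICAM1, which binds leukocyte integrins, at 1.32 ± 0.20 and E-selectin (SELE) at 1.44 ± 0.39 (median 0.48, camera adjusted p = 0.00242, and adjusted p = 0.0187 with an estimated correlation). The TNF receptor family list (6 of 30 rose, 10 when adjusted over the list alone, median 0.34, camera adjusted p = 0.00242, and adjusted p = 0.0331 with an estimated correlation) and the angiogenic list (5 of 26 rose, also 5 when adjusted over the list alone, median 0.36, camera adjusted p = 0.01, and adjusted p = 0.0331 with an estimated correlation) had medians of -0.03 and -0.01 with median scaling. The plasminogen activators PLAT and PLAU rose by 1.49 ± 0.21 and 1.10 ± 0.16. Of 36 interferon response genes 1 rose, IFIT2 at 0.95 ± 0.26, and 0 when adjusted over the list alone (median 0.32, but -0.04 with median scaling, camera adjusted p = 0.0524). With a slide block 5 rose (camera adjusted p = 0.108) and with a block for the replicate numbers 14, also 14 when adjusted over the list alone (0.0101). In the 3 pairs 26, 26 and 32 of the 36 genes were higher. The smooth muscle actin gene ACTA2 rose by 1.82 ± 0.26. In the 3 pairs the list medians were 0.33 to 1.51 for smooth muscle markers and 0.36 to 0.69 for fibroblast and pericyte markers.

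At 24 h after the single dose 2429 genes passed, 1128 higher and 1301 lower, and the groups did not overlap in 2189 of them, against 24.3% of all genes and 10% by chance. At least 2-fold changes numbered 380 higher and 179 lower. Among the largest rises NTSR2 and CCDC166, well above background on no control array, were at least 5.16-fold and 5.86-fold higher, and both lost their calls without slide 4. With a slide block 6192 genes passed, and in a fit of these 6 arrays alone 36. The count was 1616 without irradiated replicate 1, whose 75th percentile was 319.1 against 1594.9 in its control, and 1038 without slide 4, which held both; there IFIT2 and SELE also lost their calls. Without slide 4 fewer genes of the lists passed: 5 homologous recombination, 3 damage sensing, 4 mitotic and 5 heat shock genes fell, and 8 inflammatory, 2 leukocyte adhesion, 3 TNF receptor family and 1 angiogenic genes rose. The camera results of these lists still passed (adjusted p from 2.68e-12 to 0.00422), but that of homologous recombination was lost with an estimated correlation (adjusted p = 0.0743). The call of SELE ended without control replicate 1 (adjusted p = 0.0778), control replicate 3 (0.0664) or irradiated replicate 1 (0.0835), and that of IFIT2 without control replicate 1 (0.0995) or irradiated replicate 4 (0.0794). Of 59 named genes 46 lost their call in the fit of 6 arrays and 13 with normexp, among these BARD1, CCL2 and PLAU. The share of higher genes was 46.4%, but 66.8% with normexp, 35.3% with quantile normalization and 8.67% with median scaling.

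The third comparison asked what changed 6 h after the last of the 5 fractions. Interferon response genes rose together, and genes of mitosis and DNA replication fell together. All 36 interferon response genes rose, also when adjusted over the list alone (median 2.81, 2.62 to 3.02 in the 3 pairs, camera adjusted p = 5.84e-33, and adjusted p = 0.00697 with an estimated correlation). IFIT1 rose by 5.59 ± 0.59, a 48.1-fold change, from -2.001 ± 0.77 (SD, n = 3) to 3.59 ± 0.56 (SD, n = 3). Its probe, A_23_P52266, lies on chromosome 10 from 91153418 to 91153477 in hg18. The antiviral genes IFI44L and MX1 rose by 5.15 ± 0.49 and 4.99 ± 0.55, and OAS2, a sensor of viral RNA, by 3.34 ± 0.20. MX2 and RSAD2 were well above background on no control array and were at least 37.3-fold and 12.7-fold higher. Of 16 antigen processing and presentation genes 10 rose, 12 when adjusted over the list alone (median 0.75, camera adjusted p = 1.26e-05, but adjusted p = 0.0692 with an estimated correlation). The peptide transporter TAP1 changed by 1.98 ± 0.19.

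All 40 mitotic genes fell 6 h after the last fraction, also when adjusted over the list alone (median -3.25, -3.84 to -2.86 in the 3 pairs, camera adjusted p = 1.82e-51, and adjusted p = 0.0122 with an estimated correlation). CCNB1 changed by -2.94 ± 0.20, MKI67 by -3.83 ± 0.38 and the kinesin KIFC1 by -4.57 ± 0.39. Of 37 G1/S and DNA replication genes 35 fell and 0 rose, 35 when adjusted over the list alone (median -2.51, camera adjusted p = 3.38e-42, and adjusted p = 0.00385 with an estimated correlation), with MCM6 at -2.70 ± 0.11 and the replication factor CDC45 at -3.46 ± 0.20. Of 20 homologous recombination and Fanconi genes 16 fell, 17 when adjusted over the list alone (median -2.20, camera adjusted p = 3.45e-20, and adjusted p = 0.00689 with an estimated correlation). RAD54L changed by -3.13 ± 0.17. Of 19 damage sensing and end joining genes 8 fell, 9 when adjusted over the list alone (median -0.51, camera adjusted p = 0.000195, and adjusted p = 0.00689 with an estimated correlation). H2AX changed by -2.20 ± 0.24 and the checkpoint kinase CHEK1 by -1.19 ± 0.12. Of 40 p53 target genes 33 rose and 0 fell, 35 when adjusted over the list alone (median 0.95, camera adjusted p = 6.16e-15, and adjusted p = 0.0169 with an estimated correlation). FAS changed by 1.64 ± 0.09 and CDKN1A by 1.25 ± 0.27. The histone list split, with 15 of 36 genes higher and 7 lower, 15 and 8 when adjusted over the list alone (median 0.14, but -0.25 with median scaling, camera adjusted p = 0.3). H4C3 changed by -2.99 ± 0.13 and H2BC10 by 1.18 ± 0.11.

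Inflammatory and leukocyte adhesion genes rose 6 h after the last fraction. Of 26 inflammatory cytokine and chemokine genes 21 rose and 0 fell, 22 when adjusted over the list alone (median 1.62, 1.14 to 1.82 in the 3 pairs, camera adjusted p = 1.1e-12, and adjusted p = 0.000235 with an estimated correlation). The lymphocyte attractant CCL5 rose by 3.102 ± 0.27 and CCL2 by 1.38 ± 0.13. Of 15 leukocyte adhesion genes 9 rose, 10 when adjusted over the list alone (median 0.52, camera adjusted p = 0.000428, and adjusted p = 0.00689 with an estimated correlation). ICAM1 changed by 1.78 ± 0.20 and VCAM1 by 1.26 ± 0.22. Of 20 NF-kappaB regulator genes 11 rose, 12 when adjusted over the list alone (median 0.71, camera adjusted p = 0.000428, and adjusted p = 0.0469 with an estimated correlation). Of 26 TGF-beta and endothelial-mesenchymal transition genes 13 rose, also 13 when adjusted over the list alone (median 0.60, camera adjusted p = 0.000428, and adjusted p = 0.0442 with an estimated correlation). TGFB2 changed by 2.01 ± 0.33 and LTBP1 by 1.54 ± 0.21. Markers of other cell types moved with these genes. Of 9 smooth muscle markers 4 rose, 5 when adjusted over the list alone (median 1.30, camera adjusted p = 0.0289, but adjusted p = 0.118 with an estimated correlation). TAGLN changed by 1.96 ± 0.25 and ACTA2 by 1.99 ± 0.26. Of 6 fibroblast and pericyte markers 3 rose, also 3 when adjusted over the list alone (median 1.46, camera adjusted p = 0.0464, but adjusted p = 0.15 with an estimated correlation). FAP changed by 1.86 ± 0.22. Of 28 endothelial identity genes 6 rose and 2 fell, also 6 and 2 when adjusted over the list alone (median 0.08, but -0.31 with median scaling, camera adjusted p = 0.443). NOS3, the endothelial nitric oxide synthase, changed by -1.24 ± 0.13.

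In total 4258 genes passed at 6 h after the last fraction, 2235 higher and 2023 lower, and the groups did not overlap in 4230, against 57.7% of all genes and 10% by chance. Changes of at least 2-fold numbered 834 higher and 650 lower. With a slide block 7307 genes passed, with a block for the replicate numbers 7466, with normexp 1011, and in a fit of these 6 arrays alone 6902. The 4 arrays of slide 6 alone, 2 against 2, gave 3136 genes, of which 2445 were shared. The share of higher genes was 52.5%, but 39.0% with normexp and 14.1% with median scaling, which moved the median change of all genes from 0.15 to -0.24. The calls of RSAD2 and TGFB2 were lost with normexp and that of CDKN1A with median scaling.

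**Figure D2:**
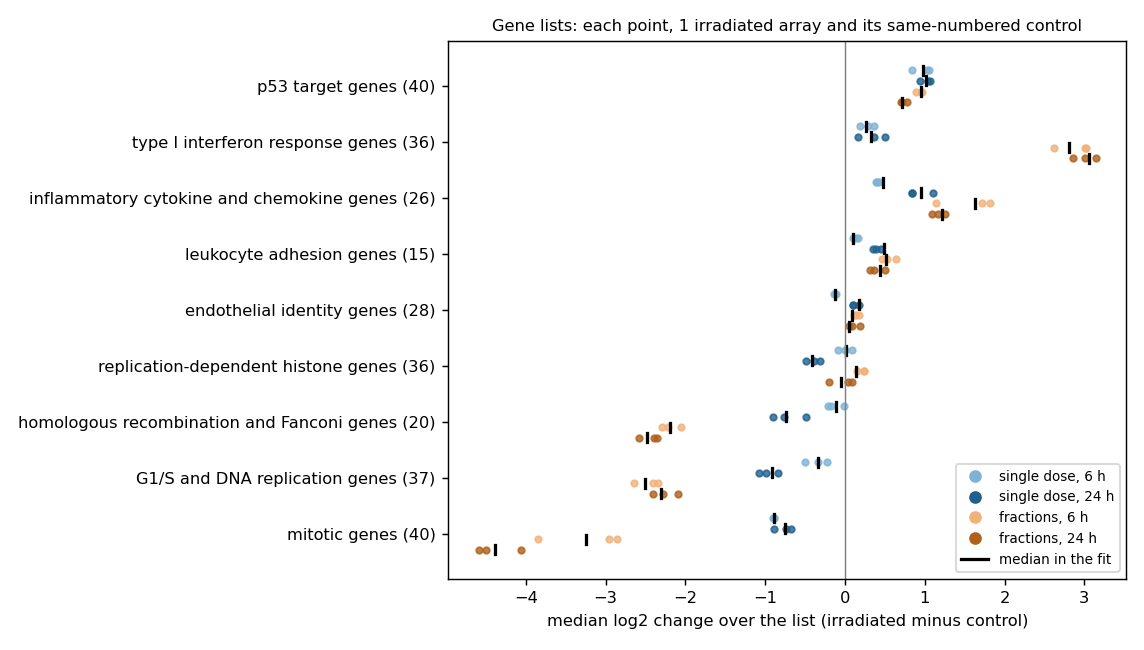
Median log2 change over each of 9 gene lists, irradiated minus control, with the number of measured genes in brackets. Each point is 1 irradiated array against the control of the same number on the same slide, and bars are the medians in the model. Interferon response genes lie at 2.62 to 3.02 at 6 h after the fractions and at 0.19 to 0.37 after the single dose. The histone median at 24 h after the single dose changes sign with normexp, and that at 6 h after the fractions with median scaling.

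The fourth comparison asked what changed 24 h after the last fraction. The mitotic genes were lower still in their medians, and the interferon response genes remained high. Some mitotic genes were well above background on no irradiated array, so the mitotic medians and levels at 24 h are not exact sizes. All 40 mitotic genes fell, also when adjusted over the list alone (median -4.38, -4.59 to -4.06 in the 3 pairs, camera adjusted p = 5.34e-72, and adjusted p = 0.00434 with an estimated correlation). CDCA3 changed by -4.60 ± 0.21, a 24.3-fold fall, and its probe A_24_P218979 lies on chromosome 12 from 6828576 to 6828759 in hg18. Cyclin B1 changed by -3.59 ± 0.20. The kinesin KIF20A, the kinetochore protein NUF2 and the topoisomerase TOP2A were well above background on no irradiated array and were at least 29.8-fold, 30.7-fold and 17.4-fold lower. Of 37 G1/S and DNA replication genes 33 fell and 0 rose, 35 when adjusted over the list alone (median -2.31, camera adjusted p = 6.17e-45, and adjusted p = 0.00282 with an estimated correlation). CDC45 changed by -4.07 ± 0.20. Of 20 homologous recombination and Fanconi genes 17 fell, also 17 when adjusted over the list alone (median -2.48, camera adjusted p = 1.62e-24, and adjusted p = 0.0036 with an estimated correlation). FANCI changed by -2.36 ± 0.14. Of 19 damage sensing and end joining genes 9 fell, 11 fell and 1 rose when adjusted over the list alone (median -0.52, camera adjusted p = 0.000202, and adjusted p = 0.00601 with an estimated correlation). The nuclear lamina gene LMNB1 changed by -2.81 ± 0.20, and HK2 and LDHA, enzymes of glycolysis, by -1.88 ± 0.19 and -1.21 ± 0.14. Of 36 genes of the histone list 13 rose and 7 fell, 14 and 10 when adjusted over the list alone (median -0.05, camera adjusted p = 0.458).

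All 36 interferon response genes rose 24 h after the last fraction, also when adjusted over the list alone (median 3.06, 2.86 to 3.14 in the 3 pairs, camera adjusted p = 1.58e-42, and adjusted p = 0.0036 with an estimated correlation). IFIT1 rose by 4.90 ± 0.59, IFI6 by 4.23 ± 0.36 and the ubiquitin-like ISG15 by 3.36 ± 0.21. Of 16 antigen processing and presentation genes 11 rose, 12 when adjusted over the list alone (median 0.84, camera adjusted p = 1.06e-07, and adjusted p = 0.0372 with an estimated correlation). HLA-C, a class I antigen, changed by 1.51 ± 0.22 and TAP1 by 1.78 ± 0.19. Of 26 inflammatory cytokine and chemokine genes 19 rose and 0 fell, 23 when adjusted over the list alone (median 1.22, camera adjusted p = 1.98e-13, and adjusted p = 0.000164 with an estimated correlation). CXCL11 changed by 3.42 ± 0.31 and CCL5 by 2.83 ± 0.27. IL6 rose by 0.94 ± 0.22, and CXCL8 had a change of 2.64 ± 0.99 that did not pass (adjusted p = 0.0712). Of 15 leukocyte adhesion genes 6 rose, 8 rose and 1 fell when adjusted over the list alone (median 0.44, camera adjusted p = 0.00256, and adjusted p = 0.0124 with an estimated correlation). ICAM1 changed by 0.86 ± 0.20. Of 40 p53 target genes 26 rose and 0 fell, 28 when adjusted over the list alone (median 0.72, camera adjusted p = 1.98e-13, and adjusted p = 0.025 with an estimated correlation). FAS changed by 1.41 ± 0.09 and CDKN1A by 1.29 ± 0.27.

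Of 26 TGF-beta and endothelial-mesenchymal transition genes 9 rose at this time, 11 when adjusted over the list alone (median 0.36, camera adjusted p = 0.000281, and adjusted p = 0.0372 with an estimated correlation). TGFB2 changed by 2.55 ± 0.33 and INHBA, a subunit of activins, by 1.799 ± 0.35. Of 16 coagulation and fibrinolysis genes 7 rose and 1 fell, 8 and 1 when adjusted over the list alone (median 0.60, camera adjusted p = 0.0064, and adjusted p = 0.0372 with an estimated correlation). The thrombin receptor THBD changed by 1.02 ± 0.15 and the protease inhibitor SERPINE2 by 1.82 ± 0.20. Of 30 TNF receptor family and apoptosis genes 9 rose and 3 fell, 11 and 3 when adjusted over the list alone (median 0.26, camera adjusted p = 0.0099, and adjusted p = 0.0451 with an estimated correlation). Of 22 cholesterol synthesis and uptake genes 9 fell, also 9 when adjusted over the list alone (median -0.49, camera adjusted p = 5.61e-05, but adjusted p = 0.13 with an estimated correlation). Of 9 smooth muscle markers 3 rose, also 3 when adjusted over the list alone, TAGLN at 3.42 ± 0.25, CNN1 at 3.68 ± 0.75 and ACTA2 at 1.85 ± 0.26 (median 0.20, but -0.32 with normexp, camera adjusted p = 0.036, but adjusted p = 0.142 with an estimated correlation). Of 6 fibroblast and pericyte markers 3 rose, also 3 when adjusted over the list alone (median 1.20, camera adjusted p = 0.0644). COL1A2 changed by 1.85 ± 0.45. The endothelial identity list had 2 of 28 genes higher and 2 lower, also 2 and 2 when adjusted over the list alone (median 0.06, camera adjusted p = 0.502).

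In total 3234 genes passed at 24 h after the last fraction, 1655 higher and 1579 lower, and the groups did not overlap in 3212, against 45.5% of all genes and 10% by chance. Changes of at least 2-fold numbered 540 higher and 569 lower. The slide block gave 6058 genes, normexp 589 (40.1% higher, against 51.2%) and median scaling 1587. The 4 arrays of slide 7 alone, 2 against 2, gave 2903 genes, of which 1861 were shared. Of 76 named genes 25 lost their call with normexp, among them CXCL11, CCL5, IL6, TGFB2, THBD, FAP, CNN1, COL1A2 and RPL5.

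**Figure D3:**
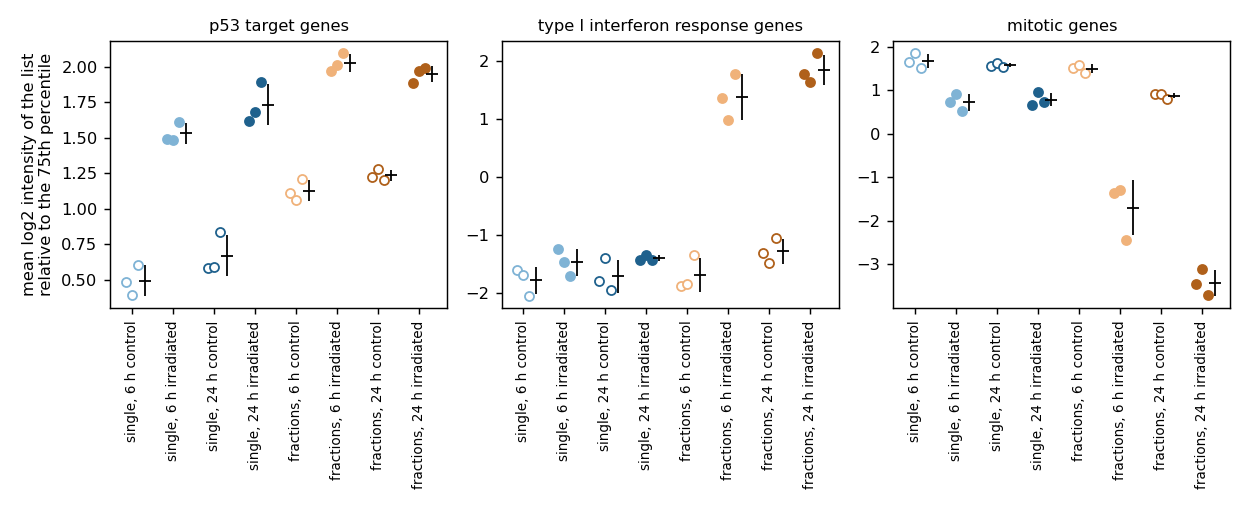
Mean log2 intensity relative to the array's 75th percentile over the p53 target, interferon response and mitotic lists, 1 point per array, with the group mean and SD (n = 3). Open points are controls and filled points irradiated arrays. The interferon list lay at 1.38 ± 0.40 at 6 h after the fractions against -1.69 ± 0.30 in its controls, and the mitotic list at -3.42 ± 0.30 at 24 h against 0.87 ± 0.06.

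Of the remaining list results given here, only those of the angiogenic and TNF receptor family lists at 6 h after the fractions and of 2 lists at 6 h after the single dose passed with an estimated correlation. The heat shock list had 0 of 16 genes called at 6 h after the single dose (limma, also 0 when adjusted over the list alone), 7 lower and 1 higher at 6 h after the fractions (9 and 1 when adjusted over the list alone, camera adjusted p = 0.00178, but adjusted p = 0.084 with an estimated correlation) and 5 lower and 2 higher at 24 h (5 and 3 when adjusted over the list alone, camera adjusted p = 0.458). The unfolded protein and integrated stress response list had 7 of 22 genes lower and 2 higher at 6 h after the fractions, 7 and 3 when adjusted over the list alone (median -0.08, camera adjusted p = 0.0381, but adjusted p = 0.369 with an estimated correlation). The serine synthesis enzyme PHGDH changed by -2.96 ± 0.24 and PSAT1 by -2.04 ± 0.19. Of 16 coagulation genes 7 rose at 6 h after the fractions, also 7 when adjusted over the list alone (median 0.46, camera adjusted p = 0.0184, but adjusted p = 0.0678 with an estimated correlation). The angiogenic list had 10 of 26 genes higher and 2 lower at 6 h after the fractions, 12 and 3 when adjusted over the list alone (median 0.57, camera adjusted p = 0.0154, and adjusted p = 0.0309 with an estimated correlation), and VEGFC, a growth factor of lymph vessels, at -1.20 ± 0.21 at 24 h. The TNF receptor family list had 10 of 30 genes higher and 1 lower at 6 h after the fractions, 14 and 1 when adjusted over the list alone (median 0.40, camera adjusted p = 0.00304, and adjusted p = 0.0309 with an estimated correlation). Of 15 Notch pathway genes 2 rose at 24 h after the fractions, also 2 when adjusted over the list alone (median 0.30, camera adjusted p = 0.271). HES4 changed by 2.16 ± 0.28.

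Of 20 senescence and secretory genes 9 rose and 3 fell at 24 h after the fractions, also 9 and 3 when adjusted over the list alone (median 0.43, camera adjusted p = 0.131). The lipid regulator ANGPTL4 changed by 1.99 ± 0.28. Of 21 hypoxia and glycolysis genes 3 fell there, also 3 when adjusted over the list alone (median -0.15, camera adjusted p = 0.0476, but adjusted p = 0.264 with an estimated correlation). Of 52 cytosolic ribosomal protein genes 5 fell, also 5 when adjusted over the list alone (median -0.20, but from -0.44 to -0.02 in the 3 pairs, camera adjusted p = 0.000176, but adjusted p = 0.487 with an estimated correlation). RPL5 changed by -0.57 ± 0.11. Of 18 immediate early genes 3 rose, 4 when adjusted over the list alone (median 0.38, camera adjusted p = 0.0376, but adjusted p = 0.323 with an estimated correlation). The reference list had 3 of 14 genes lower at 6 h after the fractions, also 3 when adjusted over the list alone (median -0.15, camera adjusted p = 0.0381, but adjusted p = 0.332 with an estimated correlation). Of 18 NRF2 oxidative stress genes 3 fell and 1 rose at 24 h after the fractions, also 3 and 1 when adjusted over the list alone (median -0.23, camera adjusted p = 0.063). Of 8 leukocyte markers 1 rose at 24 h after the single dose, 3 when adjusted over the list alone (median 0.77, camera adjusted p = 0.0485, but adjusted p = 0.23 with an estimated correlation). Without slide 4, whose pair had a median of 1.75 against 0.77 and 0.24 in the others, 0 rose (limma, median 0.46, camera adjusted p = 0.233). KRT17, 1 of the 2 measured epithelial markers, was well above background on no control array and at least 2.66-fold higher 6 h after the single dose, and this call was lost with normexp and with quantile normalization. The lymphatic list, with 2 genes measured, was not tested. At 6 h after the single dose 0 of 19 damage sensing and 0 of 15 leukocyte adhesion genes were called with limma, also when adjusted over the list alone (medians -0.07 and 0.11, camera adjusted p = 0.00769 and 0.0139, and adjusted p = 0.0461 with an estimated correlation for both). With a block for the replicate numbers 2 of the damage sensing genes fell and 2 of the adhesion genes rose, 3 and 3 when adjusted over the list alone (camera adjusted p = 0.00257 and 0.00869).

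The next comparisons asked whether the response differed between protocols. At 6 h the change differed in 1298 genes, 483 more positive and 815 more negative after the fractions. The interferon response genes changed more after the fractions by a list median of 2.59, with 33 of 36 genes past the threshold and 36 when adjusted over the list alone (camera adjusted p = 3.74e-43, and adjusted p = 0.00324 with an estimated correlation). On slide 2, which held both protocols at 6 h, this median was 2.81. The difference was 5.25 ± 0.84 for IFIT1 and 4.92 ± 0.70 for IFI44L. The mitotic genes differed by a median of -2.29, with 39 of 40 past the threshold and 40 when adjusted over the list alone (-2.01 on slide 2, camera adjusted p = 1.5e-49, and adjusted p = 0.0148 with an estimated correlation). The p53 target genes had a median difference of -0.15, with 1 gene more positive and 2 more negative, 1 and 3 when adjusted over the list alone (camera adjusted p = 0.0825). With a block for the replicate numbers 8 were more positive and 12 more negative, 8 and 14 when adjusted over the list alone (camera adjusted p = 0.0508), and with a slide block 6 and 12 (0.0449). FAS rose less after the fractions, by -0.49 ± 0.13. The mean level of the p53 list was higher in the fractionated than in the single-dose arrays, in controls (1.13 against 0.49) and irradiated arrays (2.03 against 1.53). With a slide block 3634 genes passed, with a block for the replicate numbers 3866, with normexp 198 (20.2% more positive, against 37.2%) and with median scaling 720 (9.31%). The call of FAS was lost with normexp, quantile normalization, median scaling, no filter and the mean of its probes, and also, at an adjusted p of 0.0518 to 0.0657, without control replicate 3, irradiated replicate 1 or irradiated replicate 3 of the single dose or control replicate 1, control replicate 2 or irradiated replicate 1 of the fractions.

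At 24 h the change differed between protocols in 474 genes, 168 more positive and 306 more negative after the fractions. The interferon list differed by a median of 2.56, with 32 of 36 genes past the threshold and 35 when adjusted over the list alone (2.82 on slide 5, which held both protocols, camera adjusted p = 1.3e-65, and adjusted p = 0.00148 with an estimated correlation). The mitotic list differed by -3.65, with all 40 past the threshold in both adjustments (-3.67 on slide 5, camera adjusted p = 5.41e-99, and adjusted p = 0.0024 with an estimated correlation). This median holds genes not well above background after the fractions, so it is not an exact size. TAGLN differed by 2.78 ± 0.36, TK1, an enzyme of thymidine salvage, by -4.11 ± 0.35, SELE by -2.38 ± 0.55 and the p53 target CCNG1 by -0.96 ± 0.14. The fractionated control on slide 5 was higher than the single-dose control by 3.175 for SELE and 0.4851 for CCNG1. On that slide the protocols' changes differed by -2.025 for SELE and -0.8029 for CCNG1. The gap between controls was thus the larger of the 2 values for SELE, but the smaller for CCNG1. A smaller change of SELE thus need not mean a lower level after the fractions, while CCNG1 was also lower in level on this slide. The slide block gave 1506 genes, normexp 86 (23.3% more positive, against 35.4%), median scaling 280 (51.4%) and the fit without irradiated replicate 4 of the single dose 737. The calls of SELE and CCNG1 were lost with normexp and that of CCNG1 also with median scaling, and SELE was also lost, at 0.0537 to 0.0658, without control replicate 1 or 3 or irradiated replicate 1 of the single dose or control or irradiated replicate 3 of the fractions.

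**Figure D4:**
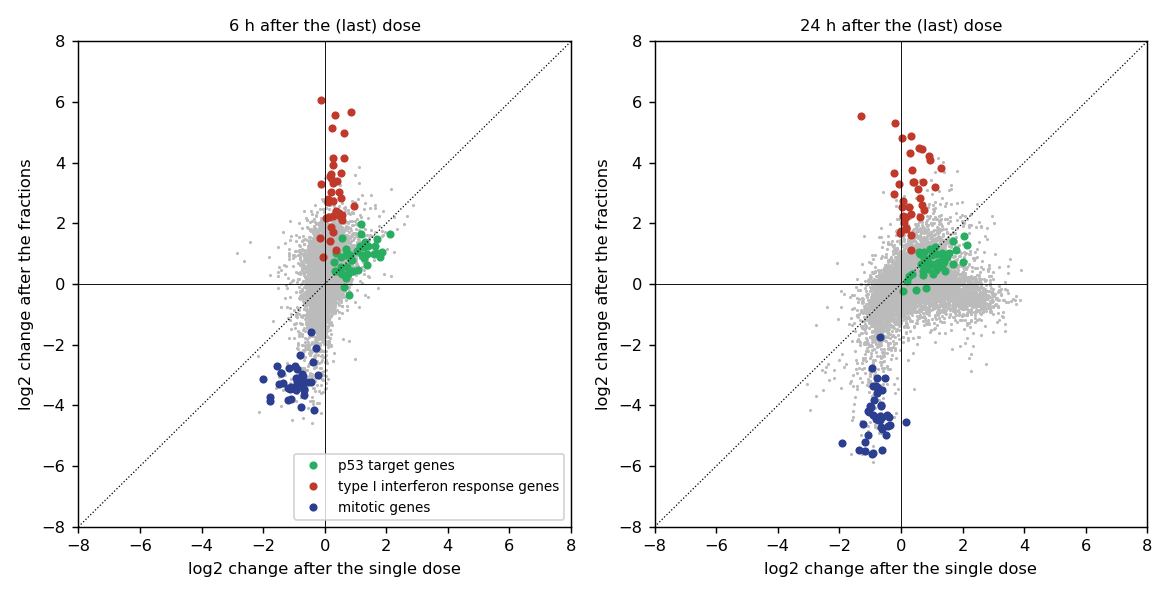
Log2 change after the fractions against log2 change after the single dose, 1 point per gene, at 6 h and 24 h. Both axes have the log2 scale, and the dotted line marks equal change. Interferon response genes (red) and mitotic genes (blue) lie away from that line, with median differences of 2.59 and -2.29 at 6 h and of 2.56 and -3.65 at 24 h.

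The 2 protocols shared calls. At 6 h 156 genes were called in both and in the same direction, 94 higher and 62 lower, where independent lists would share 15 and 8.70, and 2 were called in opposite directions, where independent lists would share 23.2. These 2, named after their values were seen, were the growth factor NRG1 (0.69 ± 0.11 after the single dose and -0.54 ± 0.11 after the fractions) and PLEKHA6 (0.62 ± 0.13 and -0.42 ± 0.13). At 24 h 1417 were shared, 799 of them lower, where independent lists would share 128 lower genes, and 17 were opposite, against 245. The comparisons had no control arrays in common, but a gene had the same error in both, from 1 model. Genes with small errors can thus be called in both without a shared response, so the counts for independent lists may be too low. That would raise opposite calls as well, and these lay under their independent counts. Across all genes, which are not independent replicates, Pearson's r of the changes was 0.42 at 6 h and 0.29 at 24 h. Spearman's rho was 0.416 and 0.425, so the lower value at 24 h depended on the measure. The shared count at 6 h was 660 with a block for the replicate numbers, 25 with normexp, 43 with median scaling and 96 with no filter, and 86 without control replicate 3, 102 without irradiated replicate 1 and 103 without irradiated replicate 4 of the single dose. At 24 h it was 299 with normexp, 650 with median scaling and 784 without slide 4.

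Between times the single-dose change differed in 70 genes, 17 more positive and 53 more negative at 24 h. Some histone genes fell more at 24 h, with H4C3 differing by -2.35 ± 0.18 and H4C2 by -2.53 ± 0.39, and 6 of 36 in the list past the threshold, 9 when adjusted over the list alone (list median -0.41, but 0.25 with normexp, camera adjusted p = 1.62e-08, but adjusted p = 0.0749 with an estimated correlation). MCM6 differed by -1.04 ± 0.16, HMMR, a spindle protein, by 1.56 ± 0.33, SMAD6, an inhibitor of BMP signalling, by 1.24 ± 0.26 and the collagen cross-linker LOX by 0.98 ± 0.19. Within slide 3, which held both times, the differences were -2.28 for H4C3, -2.59 for H4C2, -0.74 for MCM6, 1.57 for HMMR, 1.05 for SMAD6 and 0.99 for LOX. With a slide block 1256 genes passed, with normexp 3, with median scaling 6 (0% more positive in both, against 24.3%), with no filter 5, in a fit of these groups alone 1 and without slide 4 only 2. Without a single control the count was 20, 36 or 32 for replicates 1, 3 and 4 at 6 h and 26 or 17 for replicates 1 and 3 at 24 h, and without a single irradiated array 22, 15 or 149 at 6 h and 17, 25 or 189 at 24 h for replicates 1, 3 and 4. Of 12 named genes, H4C3 kept its call in every alternative run, and HMMR, SMAD6 and LOX lost theirs without 11, 10 and 6 of the 12 single arrays.

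The fractionated change differed between times in 2 genes, the kinase NEK2 and the exonuclease EXO1, both more negative at 24 h (limma, adjusted p = 0.0133 and 0.00437, with 769 genes at an unadjusted p under 0.05). Both were well above background on no irradiated array at 24 h, so the differences have only bounds, -0.45 for each. Of the mitotic genes 29 of 40 were more negative at 24 h when adjusted over the list alone and 1 over all genes (median -1.03, camera adjusted p = 1.94e-38, but adjusted p = 0.118 with an estimated correlation). Some mitotic genes were well above background on no irradiated array at 24 h, so this median is not an exact size. No slide held both times of this protocol, so no value within a slide could be had. The count was 8 with a slide block, 7 with quantile normalization and 0 with normexp (79 at an unadjusted p under 0.05). With a block for the replicate numbers it was 64, 22 more positive and 42 more negative, with 7 mitotic genes more negative over all genes. It was 1 or 32 without irradiated replicate 2 or 3 at 6 h, 1 without control replicate 1 or 2 at 24 h, and 1 or 6 without irradiated replicate 1 or 2 at 24 h. NEK2 lost its call without irradiated replicate 2 at 6 h (adjusted p = 0.0714), control replicate 1 (0.0535) or 2 (0.0654) at 24 h or irradiated replicate 1 at 24 h (0.0735). Both NEK2 and EXO1 lost theirs with normexp and in a fit of these groups alone. Median scaling and the mean of a gene's probes each ended 1 of the 2 calls.

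The controls of the protocols, which per the labels were plated in different cell numbers, differed in 2634 genes over both times, 1174 higher and 1460 lower in the fractionated controls. Of the 40 p53 target genes 27 were higher in the fractionated controls and 0 lower, 30 when adjusted over the list alone (median 0.57, and 0.70 and 0.57 on the slides that held both kinds of control, camera adjusted p = 2.07e-18, and adjusted p = 0.0172 with an estimated correlation). SESN1 was higher by 1.01 ± 0.09. G1/S and DNA replication genes were lower in 22 of 37, 25 when adjusted over the list alone (median -0.49, camera adjusted p = 5.05e-14, but adjusted p = 0.0728 with an estimated correlation), with MCM3 at -0.66 ± 0.08. Inflammatory genes were higher in 11 of 26 and lower in 2, 15 and 2 when adjusted over the list alone (median 0.58, and 0.13 and 0.69 on these slides, camera adjusted p = 7.85e-05, and adjusted p = 0.0172 with an estimated correlation). SELE was higher by 3.29 ± 0.28, the chemokine CX3CL1 by 2.63 ± 0.24, ICAM1 by 1.45 ± 0.14 and the cell cycle inhibitor CDKN1C by 2.25 ± 0.28. The share of higher genes was 44.6%, but 17.2% with median scaling, and with normexp 460 genes passed, without CX3CL1. With a slide block 3712 genes passed, and 1966 of the 2634 were among them.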

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

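Some tests were chosen only after the result was seen. These were the tests of irradiated replicate 1 at 24 h after the single dose, of scaling, of the level in the single-dose controls and of fewer endothelial cells. The fit without slide 4, the count of splits that moved irradiated arrays and the splits that kept pairs together were also chosen then. No group held enough arrays for an outlier test.

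The differences between protocols and times in this part were picked out in a test of the difference itself. The other results were not picked in this way, namely those on the controls, on the smooth muscle and fibroblast markers and on the genes at least 2-fold higher 24 h after the single dose. The radiation effect differed between protocols in 1298 genes at 6 h and 474 at 24 h, and between times in 70 genes after the single dose and 2 after the fractions.

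To test chance, irradiated arrays were regrouped among irradiated ones and controls among controls, in 100 splits drawn from 200. At 6 h 12 splits, the real one included, gave as many genes as the protocols did (highest other 4192 against 1298), and at 24 h 11 did (3781 against 474). For the times 24 splits did after the single dose (5087 against 70) and 11 after the fractions (8660 against 2). By these shares chance is not excluded for the 4 differences. The highest counts are several times the real ones and point to a structure of the samples: all irradiated arrays stayed in their own group in 11 of 11, 10 of 10, 11 of 23 and 9 of 10 of the other splits as large, so these moved controls alone and kept the difference between the irradiated arrays. Of the splits that moved irradiated arrays, 0 of 88 at 6 h (highest 2) and 0 of 89 at 24 h (highest 123) gave as many genes as the protocols did. For the times 12 of 88 and 1 of 90 did. When each control moved with its irradiated array, none of the other 9 of 10 splits gave a gene, but 10 splits are too few for a share under 0.05. For the controls of the protocols 1 of 100 splits, the real one, gave as many genes (2634, highest other 884), a share under 0.05. These splits moved arrays across slides, and slides were tied in part to protocol, so they do not separate the protocols from the slides. With a slide block 3712 genes passed, 1966 of them among the 2634.

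For the 4 comparisons of irradiated arrays with controls there are 10 splits each, too few for a share under 0.05, and in each only 1 split, the real one, gave as many genes. The counts were 177 (highest other 1), 2429 (1440), 4258 (0) and 3234 (0). The split with 1440 genes, 24 h after the single dose, set the pair of slide 3 apart from the pair of slide 5, and the slide block gave 6192 genes.

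Interferon response genes changed more after the fractions than after the single dose, relative to controls, by a list median of 2.5857 at 6 h (adjusted p = 3.74e-43) and 2.5624 at 24 h (1.3e-65). A slide or hybridization batch was argued against by the slides that held both protocols, where the median was 2.808 at 6 h and 2.818 at 24 h. A higher level in the single-dose controls was argued against by the controls, where the fractionated minus the single-dose median was 0.2278 over all slides, -0.09632 on slide 2 (14 genes higher, 22 lower) and 0.03204 on slide 5 (21 and 15), all small against 2.5857. With these technical explanations argued against, a candidate explanation is a response to fractionated dosing, as a hypothesis found and tested on the same data. The number of cells plated and the time since the first dose also differed with the protocol and were not tested apart.

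Some smooth muscle and fibroblast markers rose after the fractions, 4 of 9 and 3 of 6 at 6 h and 3 of 9 and 3 of 6 at 24 h. The pair medians of these lists were also above 0 at 24 h after the single dose (0.33 to 1.51 and 0.36 to 0.69). The fibroblast list did not pass at 24 h (camera adjusted p = 0.0644), the other list calls were lost with an estimated correlation (adjusted p = 0.118, 0.15 and 0.142), and the smooth muscle median at 24 h was -0.32 with normexp. Cells of another type in the cultures at 24 h were argued against only in part. Of 26 markers 13, among them the abundant COL3A1, LUM and THY1, were well above background on no irradiated array, while 10 were on every one. This argues against cells that express these 3 genes strongly. It cannot decide on smooth muscle cells, since the count pools both lists. ACTA2, TAGLN, CNN1, SMTN and SYNM were well above background on every irradiated array, and MYH11, MYOCD, LMOD1, ACTG2 and SYNPO2 on none. Fewer endothelial cells at 24 h stay open. The test took 7 markers measured on every array and no brighter than TAGLN in the controls. Their changes lay up to 3.991 ± 0.5011 apart (TAGLN 3.417, POSTN -0.5742), with a median of 1.849 and 2 at or below 0. It cannot decide, since markers of several cell types need not change alike. A change of some of these genes within the endothelial cells may also remain, as a hypothesis found and tested on the same data.

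Genes at least 2-fold higher 24 h after the single dose numbered 380, against 179 lower. Irradiated replicate 1 was weak against its control, with a 75th percentile of 319.1 against 1594.9. That control was the brightest of all arrays, and irradiated replicate 3 was weaker still (248.8). Irradiated replicate 1 was argued against as the whole cause: without it 62.89% of the 380 still passed and were higher. The share was 60% to 94.74% without another array, the bright control among them, and 44.47% without slide 4. The 380 were picked in a fit that held irradiated replicate 1. Its median spot signal lay at -2.70 (log2) relative to its 75th percentile, against -3.51 in its control. In the other pairs it was -3.19 against -3.40 and -3.22 against -3.30. A rise of dim signals with this shift was not separated. Scaling on the 75th percentile stays open: with median scaling 53.95% still passed, and the median of the 380 went from 1.342 to 0.9786. All 380 kept their sign, but this could not fail. That scaling shifts every gene by the same amount, which is smaller than the 2-fold cut by which they were picked. No biological explanation was tested for this pattern.

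Between protocols at 6 h, the fractionated minus the single-dose change was 6.216 for MX2, 5.247 for IFIT1, 4.916 for IFI44L, 4.827 for RSAD2 and 4.355 for MX1 among higher genes, and -4.15 for KIFC1, -4.109 for RRM2, -3.815 for SGO1, -3.723 for E2F8 and -3.718 for CLSPN among lower ones (adjusted p from 3.6e-06 to 0.00383). MX2, RSAD2, E2F8 and CLSPN were well above background on no array of at least 1 group, so these are not sizes: with such groups at the lowest signal above background the bounds were 4.957 for MX2, -2.724 for E2F8 and -1.48 for CLSPN, and RSAD2 had no bound. It was -0.4864 for FAS, -1.135 for ASCC3, 0.809 for SPATA18, -2.895 for H4C3, 2.842 for CCL5, 2.75 for CXCL11 and 1.159 for ICAM1 (adjusted p from 1.02e-07 to 0.0365). For TAGLN it was 1.956 (0.00148). Of these 18 calls normexp ended 13, those of MX2, RSAD2, KIFC1, SGO1, E2F8, CLSPN, FAS, ASCC3, SPATA18, CCL5, CXCL11, ICAM1 and TAGLN. Median scaling ended those of FAS, SPATA18 and ICAM1, and a fit of these groups alone those of FAS, SPATA18 and ASCC3. FAS and SPATA18 were also lost with quantile normalization and no filter, and without 6 and 9 of 12 single arrays (adjusted p up to 0.0657 and 0.102), and FAS with the mean of its probes. List medians were -2.0128 for homologous recombination and Fanconi genes, -0.38598 for damage sensing and end joining, -1.9434 for G1/S and DNA replication, -2.2912 for mitotic, 0.91253 for inflammatory, 0.38744 for leukocyte adhesion, 0.50366 for TGF-beta and endothelial-mesenchymal transition and 0.50509 for angiogenic genes (camera adjusted p from 1.5e-49 to 0.00419). On slide 2 these lists gave -2.04, -0.354, -2.09, -2.01, 1.01, 0.538, 0.553 and 0.493.

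At 24 h the difference between protocols was 6.842 for RSAD2, 5.494 for MX2, 4.77 for IFI44L, 4.553 for IFIT1 and 4.027 for IFITM1, and -4.958 for PIMREG, -4.851 for NEK2, -4.708 for HMMR, -4.66 for KIF20A and -4.655 for BUB1B (adjusted p from 4.42e-07 to 0.00685). With groups not well above background treated in this way the bounds were 3.788 for RSAD2, 4.452 for MX2, -3.246 for PIMREG, -2.617 for NEK2, -4.006 for KIF20A and -3.43 for BUB1B. It was -0.9619 for CCNG1, -0.7527 for SESN1, -4.106 for TK1, -2.379 for SELE and 1.093 for H2BC11, which is -0.47 with normexp (adjusted p from 1.4e-06 to 0.0206). The fractionated control on slide 5 was higher than the single-dose control by 0.4851 for CCNG1, 0.7493 for SESN1 and 3.175 for SELE. TAGLN differed by 2.782 (5.93e-05), while the smooth muscle list did not pass (camera adjusted p = 0.306, median -0.01932 on slide 5). Normexp ended the calls of RSAD2, MX2, CCNG1, SESN1, H2BC11 and SELE, and median scaling those of CCNG1 and SESN1. SESN1 was also lost with no filter, a fit of these groups alone and without 3 of 12 single arrays (0.068 to 0.0711), and SELE without slide 4 and without 5 single arrays (0.0537 to 0.0658). List medians were -1.8291 for homologous recombination and Fanconi genes, -1.2197 for G1/S and DNA replication and -3.6517 for mitotic genes, 0.56841 for histones, which is -0.01 with normexp, and 0.30803 for inflammatory genes, which is -0.42 with normexp (camera adjusted p from 5.41e-99 to 0.0021). On slide 5 these lists gave -2.11, -1.51, -3.67, 0.593 and 0.396.

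Between times the single-dose change at 24 h minus that at 6 h was 2.234 for PSG1, 1.817 for KLHDC9, 1.56 for HMMR, 1.521 for EBI3, 1.237 for SMAD6 and 0.9761 for LOX, and -2.966 for H4C4, -2.533 for H4C2, -2.352 for H4C3, -2.328 for H4C13, -2.031 for FAM111B and -1.036 for MCM6 (adjusted p from 3.36e-06 to 0.0496). Of these 12 genes H4C3 alone kept its call in every alternative. A fit of these groups alone ended the other 11, the fit without slide 4 these but FAM111B, and normexp these but H4C2 and H4C13. Median scaling and no filter each ended those of PSG1, KLHDC9, HMMR, EBI3, SMAD6, LOX and MCM6, quantile normalization those of PSG1, KLHDC9, EBI3 and SMAD6, and a filter on all arrays that of H4C4. The values of the deposited table ended EBI3 and SMAD6, and an intensity trend EBI3. Without 1 of 12 arrays PSG1 was lost in 6 cases, HMMR in 11, EBI3 in 10, SMAD6 in 10 and LOX in 6 (adjusted p up to 0.165). List medians were 0.52164 for inflammatory and 0.37162 for angiogenic genes (camera adjusted p = 0.000251 and 0.00221), and 0.34 and 0.355 on slide 3. The fractionated change differed by -2.681 for NEK2 (adjusted p = 0.0133) and -2.33 for EXO1 (0.00437), with bounds of -0.4467 and -0.4499, since neither was well above background on an irradiated array at 24 h. NEK2 lost its call without 4 of 12 single arrays (0.0535 to 0.0735). Both genes lost theirs with normexp and in a fit of these groups alone. Median scaling and the mean of a gene's probes each ended 1 of the 2 calls.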

How the results depend on the processing

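The fit without slide 4 was chosen after the data were seen. Counts are given in the order single dose 6 h and 24 h, fractions 6 h and 24 h, protocols at 6 h and 24 h, times for the single dose and the fractions, and controls, for those beyond 1.5 times the reported 177, 2429, 4258, 3234, 1298, 474, 70, 2 and 2634; for these, and for the shared counts, the cause was not tested.

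Normexp gave 27 genes, 1011 and 589 for the fractions, 198 and 86 for the protocols, 3 and 0 for the times (limma, 79 at an unadjusted p under 0.05 for the fractions) and 460 for the controls. Median scaling gave 52 at 6 h after the single dose, 1587 at 24 h after the fractions, 720 and 280 for the protocols and 6 and 1 for the times. Quantile normalization gave 106 and 7 for the times. With no filter on dim probes there were 114 at 6 h after the single dose and 5 for the single-dose times, and with a filter on all arrays 0 for the fractionated times (limma, 513 at an unadjusted p under 0.05). The mean of a gene's probes gave 1 for the fractionated times. A fit of only the groups compared gave 0 (limma, 726 at an unadjusted p under 0.05) and 36 for the single dose, 6902 at 6 h after the fractions and 1 for each of the times. The replicate block gave 766, 6186, 7466, 6284, 3866, 1672, 1548 and 64, the slide block 612, 6192, 7307, 6058, 3634, 1506, 1256 and 8, the scan day block 578, 5715, 6832, 5681, 3292, 1368, 1052 and 15, and array weights 1707, 8622, 6300, 5072, 989, 995, 511 and 5027 (without the 24 h single dose, which stayed within 1.5 times). The scan day block gave 4482 for the controls. Without slide 4 there were 1038 genes at 24 h after the single dose, of which 1018 were shared, and 2 for its times.

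Leaving out 1 array gave 96 to 186, 1616 to 3546, 3054 to 3600, 2335 to 2828, 946 to 1524, 368 to 737, 15 to 189, 1 to 32 and 1846 to 2661 genes. The genes shared by the protocols, 156 at 6 h and 1417 at 24 h, numbered 86 to 173 and 1053 to 1697 without 1 array. At 6 h the shared count was 25 with normexp, 43 with median scaling, 96 with no filter, 660 with the replicate block and 85 at an adjusted p under 0.01, and at 24 h 299 with normexp, 650 with median scaling, 3758 with the replicate block, 784 without slide 4 and 687 at an adjusted p under 0.01. Normexp moved the median change of all genes to 0.30 at 24 h after the single dose and 0.17 at 6 h and -0.10 at 24 h after the fractions, and median scaling to -0.27 at 24 h after the single dose. For the protocols at 24 h, the times of each protocol and the controls it was -0.31, 0.24, -0.13 and 0.18 with normexp, and with median scaling 0.38, -0.26, 0.40 and -0.12, and -0.25 for the protocols at 6 h.

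No call of a named gene was reversed in the alternatives run, and no list call in those run for lists. The lists were not tested with normexp or median scaling, where some list medians changed sign. Of 313 calls of named genes 110 were lost with normexp, 102 with only the groups compared, 47 with median scaling, 22 with no filter and 16 with quantile normalization, and 161 of 2292 values without 1 array. Of 127 called list results 64 held with an estimated correlation, 122 with quantile normalization and 117 with the slide block. With fry in place of camera 105 passed in the same direction, but fry tests a list against no change and camera against the other genes.

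Signal over background limits what can be seen, since 47.5% to 69.9% of probes were well above background on an array. In simulated data with changes of 0.5, 1 and 2 (log2), for the comparison at 6 h after the single dose 9 of 67, 37 of 67 and 57 of 66 genes were called, with 6 false calls, and for the fractionated times 3 of 67, 19 of 67 and 44 of 66, with 3 false calls. The simulated noise was independent and had no background limit, so these rates do not describe that limit.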

Other observations

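The values here were looked for after the results were seen. In all 4 comparisons of irradiated arrays with controls 119 genes were called, 118 of them in the same direction, 72 higher and 46 lower. Of these 118, 72 had a symbol and were in no list. Examples, as changes 6 h and 24 h after the single dose and 6 h and 24 h after the fractions, were VWCE (1.75, 2.59, 2.25 and 1.90), TMEM217 (1.40, 2.01, 2.16 and 2.02), PSTPIP2 (1.85, 2.01, 1.58 and 1.31), CDCA7 (-1.37, -1.86, -3.02 and -2.72), SGO2 (-1.22, -1.37, -2.59 and -2.75) and CDKN2C (-0.99, -1.43, -3.44 and -3.35).

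Of 17 genes called in opposite directions at 24 h, 4 were histone genes of the H2A and H2B families. H2AC21 changed by -0.46 after the single dose and 0.51 after the fractions, and H2BC17 by -0.43 and 0.64. H2BC9 changed by -0.47 and 0.57, and H2BC3 by -0.44 and 0.53, the last with another sign under another scaling or background correction.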
